A study of Mus musculus with 6 samples.

How the data were processed

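Live CD45+ cells sorted from the lungs of mice with a humanized PD-1 were profiled by droplet-based single-cell RNA sequencing on the 10x Genomics Chromium platform, and the labels state that 3 samples per treatment were mixed by cell hashing, with about 50000 cells per treatment, against 12448 and 13728 distinct barcodes in the tables and 10310 and 11164 cells kept. Cell hashing marks each mouse with an antibody-bound tag. No hashtag measurement was used here, so cells could not be assigned to a mouse. The submitters' processing notes name Partek and the mm10 assembly. The aligner, the counting method and their versions are not given in the sources used here.

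The deposited tables hold 1 record per cell and 20882 gene columns of estimated counts, which are expected counts of molecules that need not be whole, as made by the authors with no normalization evident from the values. Per the file headers, each record also has the authors' total count, their count of expressed genes, and the percent of mitochondrial and of ribosomal reads. A column of the authors marks cells as positive for Cd3e or leaves them outside a filter. Cells that passed it held 500 to 4000 genes and at most 14912 counts, as observed in the files, and this filter was adopted. Expected counts were rounded to whole numbers after summing over cells.

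The labels present 6 samples, 3 isotype and 3 PD-1 agonist, and a test of 3 against 3 with edgeR's quasi-likelihood method was fixed before the data were examined. It could not be used as written. The 3 tables of a treatment shared 2373 to 2736 barcodes per pair, with a cosine similarity of 0.779 to 0.814 between the profiles of the same barcode in 2 tables, against 0.402 to 0.44 for different barcodes. The number of barcodes found in all 3 tables was 1176 and 856, close to the 1115 and 853 given by random subsets of 1 pool. Each treatment was therefore treated as 1 sample of 1 pool, and no p-value, standard error or count of changed genes was computed. The rules that replaced the plan were written after the shared barcodes, the total counts, the number of Cd3e-flagged cells and the share of cells with counts of several marker genes had been seen per table, but before any ratio of expression or share of a cell class had been computed.

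Each barcode was taken from the table with its highest total, giving 12448 isotype and 13728 agonist cells, of which 11106 and 12216 passed the filter. Doublets, droplets with more than 1 cell, were called with Scrublet in scanpy 1.11.5 (expected rate 0.1, score threshold 0.25), and the 796 (7.17%) and 1052 (8.61%) called cells were removed, leaving 10310 and 11164. Cells of both libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), and lymphoid cells were clustered again. Clusters were named "-like" from 25 marker lists fixed before the data were examined, with at least 3 detected markers. The thresholds of the naming rule were revised after the clusters, their leading genes and their cell numbers had been seen, in 2 rounds, and the first version is among the alternatives. In total 8 clusters stayed unnamed, with 8.62% of the isotype cells and 7.86% of the agonist cells.

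Counts were summed per library and cell class. Totals were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, used for these factors only. A gene entered a comparison with at least 50 counts over both libraries. Ratios have exact Clopper-Pearson intervals, levels have exact Poisson intervals and shares exact binomial ones, at the 95% level, and a floor of 3 counts stands in for 0. Intervals treat molecules as independent and cover counting error only, so they are too narrow where 1 cell holds much of a gene's count. For 64 of the 194 named gene and class pairs, 1 cell held at least 25% of the counts of a library, a threshold chosen after such shares had been seen, and values without the top cells are given for several of them. Counting was tested on simulated sums for all T cells, where 95.4% of the intervals of unchanged genes among 11117 genes held the truth and simulated log2 changes of 1 and 2 were recovered as 0.99 and 1.97. That simulation did not include counts concentrated in 1 cell.

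Genes were ranked by the bound of the interval nearest to no change, and 12 in each direction were named for all T cells and 5 for other classes. The first result of this rule was mostly pseudogenes and ribosomal protein genes. After those values had been seen, a filter to protein-coding genes without ribosomal, histone and unnamed genes was tried, and it still named multi-copy genes. With its values seen as well, the rule was limited to protein-coding genes with under 10% of the 31-mers of their longest transcript in another gene, computed from a GENCODE annotation of GRCm38, the assembly also called mm10. Of the 20882 gene columns, 20460 matched 1 annotated gene by name. By this measure 10542 coding genes were under the threshold and 2868 at or over it, and the latter are called uncertain in the text. Immunoglobulin and T cell receptor segments, Xist and Y-linked genes were not named. A set of cytokine, receptor and chemokine genes and 39 gene lists, 4 of them for free RNA, were fixed before the data were examined. Up to 4 members of a list are given by the same bound. A gene fixed in advance and a test written in advance of RNA from neutrophils as a source of the naive and memory pattern are not reported here.

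A list is described where its median lay at or below percentile 1, or at or above percentile 99, of 10000 random lists in the T cell classes and in neutrophils, and the list of type II interferon response genes is described in every class. An earlier selection of lists made by hand after all values had been seen left out some beyond those percentiles and was dropped. This choice of classes, and the choice of the classes whose named genes were recomputed under the alternatives, were made after the values had been seen. Of 513 measured pairs of list and class, 124 lay beyond those percentiles and 54 are described. The tests of technical explanations at first departed in 3 places from what had been written in advance. They were revised towards it after their values had been seen, and 1 verdict, that on sequence shared with other genes, moved from excluded to open. For that verdict the rule written in advance was not followed exactly. It set a bound for the ratio alone, and the ratio lies under it. The verdict of open rests on the interval of the ratio, which reaches past the bound. Alternatives fixed in advance were RLE factors, no filter on low counts, doublets kept, a stricter filter on cells (at least 500 genes and under 5% mitochondrial counts), Leiden resolution 2, free RNA genes left out, other denominators of shares, and leaving out each table. Those chosen after seeing the data were plain totals, TMM over genes without shared sequence, lists without such genes, the first naming rule, the authors' Cd3e flag in place of the T cell class, the top cells left out, and some of the former applied to further results. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.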

Results

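Single-cell RNA sequencing was used to profile live CD45+ cells, the leukocytes, sorted from the lungs of mice that carry a human form of PD-1, the inhibitory receptor of activated T cells. The mice had received either an isotype control antibody or an antibody that acts as an agonist of PD-1, and the title of the study asks how the agonist reprograms T cells in neutrophilic asthma. Each treatment was represented by 3 tables, labelled as mouse 1 to 3. They held 6481, 6438 and 6393 cell records with 29092621, 29749815 and 24867171 counts for isotype, and 6615, 6749 and 6668 records with 25572101, 24987046 and 21556545 counts for the agonist. The 3 tables of a treatment were found to share cells. Between 2373 and 2736 barcodes were common to any 2 tables of the same treatment (35.9% to 42.5% of the smaller table), against 3 to 13 (0.047% to 0.201%) for tables of different treatments. The total counts of a shared barcode ranked almost identically in both tables (Spearman correlation across cells 0.9994 to 0.9996), and the counts of the tables differed by less than sampling noise, with a variance of 0.492 to 0.551 times the binomial. The tables of a treatment were therefore counted as 1 sample, and each barcode was used once.

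With 1 independent sample per treatment, no test between treatments was possible, no difference has a replicate check, and treatment cannot be told apart from library. The values compare these 2 libraries, not the treatments. Intervals are exact at the 95% level and cover counting error only. Levels are given as CPM, counts scaled to a common library total with TMM factors. Ratios are log2 of agonist over isotype, so that negative values are lower in the agonist library. Members of a list are counted as higher or lower by the sign of their ratio, also where it lies within counting error. A gene list is described by its median log2 ratio, with an interval from redrawing the counts of its fixed members with Poisson error. That interval covers counting error only, not the spread between genes. The list also has the percentile of its median among 10000 random lists of the same size matched on mean expression. Random lists were drawn gene by gene, while members of a list can vary together. A percentile therefore describes a list, holds no spread between samples and is not a test between treatments.

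The first comparison asked which leukocytes made up the lung after each treatment. Neutrophil-like cells, the granulocytes for which neutrophilic asthma is named, were 17.1% of the isotype cells (16.4% to 17.8%) and 19.4% of the agonist cells (18.7% to 20.1%). T cell-like cells were 22.6% (21.8% to 23.4%) and 19.6% (18.9% to 20.4%), a log2 ratio of -0.20. Within the T cells, regulatory T cell-like cells, the suppressive Foxp3 lineage, were 6.43% of the isotype T cells (5.47% to 7.50%) and 4.92% of the agonist T cells (4.06% to 5.92%). Gamma-delta T cell-like cells, an innate-like lineage that includes interleukin 17 producers, were 13.6% (12.2% to 15.05%) and 11.4% (10.1% to 12.8%). Their cluster led by Tcrg-C2 and Klra6, with only 3 gamma-delta markers detected, was 8.57% and 6.57% of T cells (-0.38, -0.70 to -0.07). The cluster led by Blk, with Il23r and 9 markers detected, was 5.0% and 4.8% (-0.07, -0.46 to 0.33). CD4 T cell-like cells were 31.8% (29.96% to 33.8%) and 37.9% (35.9% to 40.0%). B cell-like cells were 16.1% and 17.6% of all kept cells, and interstitial macrophage-like cells 9.61% and 8.03%. The main macrophage cluster was 7.97% and 7.17% (-0.15, -0.29 to -0.01). The other, of 169 and 96 cells with a median of 1152 counts, was at -0.93 (-1.31 to -0.56). NK cell-like cells were nearly equal at 10.9% (10.3% to 11.5%) and 10.9% (10.4% to 11.5%). The sort for CD45 sets which cells could be seen, and the agonist cells were shallower, with a median of 2212 counts per kept cell against 2537. CD8 T cell-like cells were 40.6% and 40.1% of T cells, but this ratio depended on the clustering, reaching -0.49 at a finer resolution, and the gamma-delta ratio of -0.26 came to -0.01 under the first rule used to name clusters. With doublets kept, the gamma-delta ratio was -0.17 and the CD4 ratio 0.12 in place of 0.25.

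**Figure D1:**
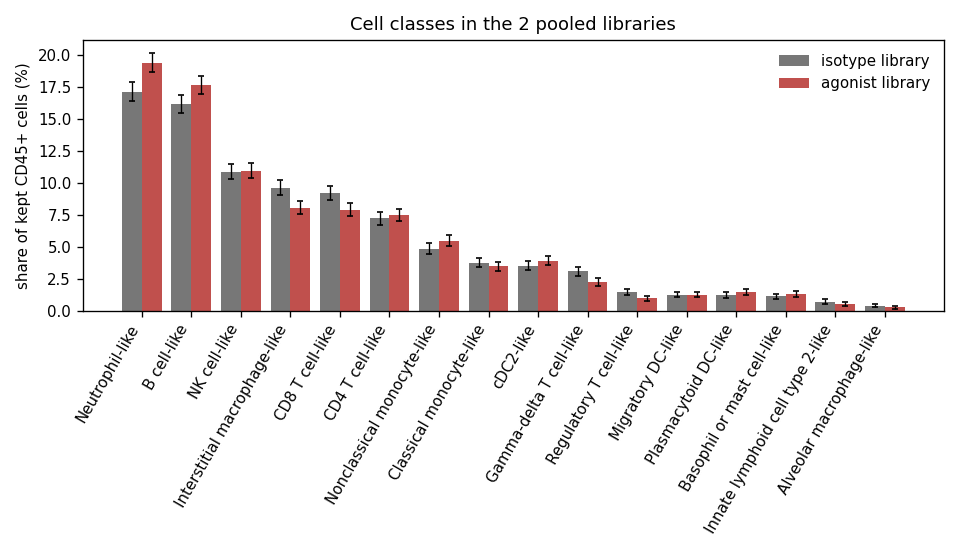
Share of kept cells, in percent, of each cell class in the isotype library and in the agonist library; bars are exact 95% binomial intervals, which cover counting error only, with 1 library per treatment. Neutrophil-like cells were 17.1% and 19.4%, and T cell-like cells 22.6% and 19.6%.

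The second comparison asked how the T cell transcriptome differed between treatments. Genes of the naive and memory state, whose products keep T cells circulating through lymphoid tissue, were higher in the agonist library in 12 of 12 measured members (median log2 ratio 0.27, 0.24 to 0.30, percentile 99.9). S1pr1, the sphingosine 1-phosphate receptor that lets lymphocytes leave tissue, was at 343 CPM in the isotype library (330 to 356) and 471 in the agonist library (455 to 488). Ccr7, the lymph node homing receptor, was at 406 (392 to 420) and 544 (526 to 562), and the transcription factor genes Bach2 and Satb1 had log2 ratios of 0.46 and 0.26. Igfbp4 of this list also leads a cluster of 21.6% of the isotype and 27.2% of the agonist T cells. Ccr7 and Dapl1 lead one of 18.7% and 23.7%. With T cell clusters weighted equally in both libraries, the median of the list was 0.0934. Genes of the type 1 helper program were lower in 8 of 10 members (median -0.24, -0.37 to -0.13, percentile 0.01), among them the chemokine receptor gene Cxcr3 (-0.56) and the chemokine gene Ccl5 (-0.34). Genes of proliferation were lower in 26 of 28 members (median -0.27, -0.31 to -0.20, below all 10000 random lists), including Top2a (-0.37), a topoisomerase of dividing cells, and Mcm5 (-0.35), a part of the replicative helicase. Top2a leads a cluster of dividing T cells that was itself smaller in the agonist library (138 and 97 cells, 5.92% and 4.42% of T cells, log2 ratio -0.42, -0.81 to -0.03). Without the isotype mouse 3 table, the list's median was -0.14 and Top2a was at -0.23.

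Pdcd1, which encodes PD-1 itself, was among the lower genes. The deposited tables named it by symbol, and the annotation of the mm10 assembly places it on chromosome 1 at 94038305 to 94052553 (ENSMUSG00000026285). It was at 49.1 CPM in the isotype T cells (44.4 to 54.2, from 401 counts) and 29.8 in the agonist T cells (25.8 to 34.3, from 195 counts), a log2 ratio of -0.72 (-0.97 to -0.47). The ratio was -1.16 in the kept cells of any class with the authors' Cd3e flag. Because the mice carry a human PD-1 and reads were counted on the mouse genome, part of this transcript may be missing from both libraries. Per class, Pdcd1 had 85 and 47 counts in CD4 T cell-like cells (-0.88, -1.42 to -0.35, or -1.47 at the finer resolution), 132 and 46 in CD8 T cell-like cells (-1.11, -1.62 to -0.61) and 19 and 6 in regulatory T cell-like cells (-1.25, -2.86 to 0.13, where 1 cell held 83.3% of the agonist counts). In gamma-delta T cell-like cells the difference was within counting error (-0.26, -0.68 to 0.16, and 0.18 under the first naming rule), and in NK cell-like cells the gene was higher in the agonist library (32 and 52 counts, 0.73, 0.06 to 1.41). Over all CD45+ cells it was lower (493 and 314 counts, -0.58, -0.79 to -0.38). The CD8 value depended on the clustering. The CD8 class included a cluster of 175 and 107 cells led by Pdcd1, Gzmk and interferon genes, and this cluster's name was not stable. When doublets were kept, 5 and 7 of its cells stayed in the CD8 class, 111 and 56 were named CD4 T cell-like, and the log2 ratio of Pdcd1 in CD8 cells was 0.52. At the finer resolution it was -0.52. Transcripts of the PD-1 ligands were near equal in T cells, with log2 ratios of -0.12 for Cd274 (-0.30 to 0.06, a gene that shares sequence with others and is uncertain) and -0.03 for Pdcd1lg2 (-0.52 to 0.45).

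Among the protein-coding genes of T cells with little sequence in common with other genes, 12 in each direction were named by the size of the ratio after allowing for counting error. Slc15a2, which encodes a proton-coupled peptide transporter, led the higher ones with 13.8 CPM in the isotype library (11.4 to 16.6) and 36.7 in the agonist library (32.2 to 41.7). It lies on chromosome 16 at 36750177 to 36784962 (ENSMUSG00000022899), and its counts were spread over 99 isotype and 197 agonist cells. Pik3ip1, an inhibitor of phosphoinositide 3-kinase, had a log2 ratio of 0.60 (0.42 to 0.78), Prkca, a protein kinase C, 0.57 (0.38 to 0.76), Arhgap31 0.55, and Tomm20, a mitochondrial import receptor, 0.62. The others were the chemokine gene Ccl9 (1.57, 0.86 to 2.32, or 0.89 with doublets kept), the aldose reductase gene Akr1b3 (0.87), the calmodulin kinase gene Camk2b (0.88) and Plekhg1 (1.32, or 0.95 without the top cell of each library, as 1 agonist cell held 29.5% of its counts). S100a8 (0.93) and S100a9 (0.79), the major calcium-binding proteins of neutrophils, completed the 12 with S1pr1. In lists that hold these genes, 4 of 5 free RNA markers of neutrophils were higher (median 0.72, percentile 99.8, or 0.33 without a filter on low counts). So were 5 of 8 neutrophil granule genes (median 0.30, -0.03 to 0.48, percentile 99.6), whose median was 0.096 without the agonist mouse 1 table and -0.18 without the free RNA genes. The T cells include an unnamed cluster of 38 and 28 cells whose leading genes hold 1 neutrophil marker, Mmp9, beside Il4 and Il17rb. S100a8 and S100a9 are not among them. In all kept cells with the authors' own Cd3e flag, S100a8 and S100a9 were instead lower, at -1.29 and -1.20, and the free RNA median was -1.51. That set is not limited to T cells. The flag marked 37.1% of an unnamed cluster led by S100a8 and S100a9 (14 and 21 cells), and 0.73% and 1.0% of the larger neutrophil clusters. It marked 52.6% of a CD4 T cell-like cluster. A reversal within T cells is therefore not shown.

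The lower T cell genes included Gzmk, a granzyme of effector cells (-0.90, -1.34 to -0.47), Areg, the growth factor amphiregulin (-0.77, -1.03 to -0.51, or -0.19 with the Cd3e flag), the spindle gene Aspm (-0.84), the heat shock gene Hsph1 (-0.60, -0.77 to -0.43), the formin gene Fmnl3 (-0.99), the transcription factor gene Mybl1 (-1.34), Lrr1 (-1.24, or -0.80 without the isotype mouse 2 table) and Tmem88 (-0.99). Nrgn, a calmodulin-binding protein, had 104 and 9 counts (-3.21, -4.38 to -2.23, or -1.60 with the Cd3e flag), and it is also a leading gene of an NK cell-like cluster. Gzmk and Areg likewise lead T cell clusters. Several cytokine genes rested on few cells. Ifng, the gene of interferon gamma, had 874 and 325 counts (-1.11, -1.29 to -0.92), but 1 isotype cell held 30.8% of them and the ratio without the top cells was -0.69. Ifng shares 16.5% of its sequence with other genes and is uncertain. Tnf was at -0.81, or -0.49 without the top cells, and Il17f at -1.36, which became 0.53 without them and -0.09 with the Cd3e flag. In the isotype library 1 cell held 81.2% of its counts.

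Other cytokine and regulator genes fixed in advance gave a mixed picture. Il17a, the signature cytokine gene of type 17 helper cells, was at 0.29 (213 and 209 counts, 0.01 to 0.58), but at 0.05 without the agonist mouse 3 table and -0.36 in the kept cells of any class with the authors' Cd3e flag. The type 2 cytokine gene Il4 was at -1.36 (32 and 10 counts, -2.55 to -0.30), but at 0.19 with that flag. It is among the leading genes of the unnamed T cell cluster that also holds Mmp9 and Il17rb. Il13 was not distinguishable at this depth (-0.26, -1.35 to 0.78). Il5 had 8 and 0 counts, and 87.5% of the isotype counts came from 1 cell. Il2, the T cell growth factor gene, was lower (-0.90, -1.41 to -0.40, or -0.57 without the agonist mouse 1 table), Il10 was at -0.61 (-1.27 to 0.02), and Foxp3, the regulatory T cell transcription factor, was near equal (-0.10, -0.36 to 0.15). Csf2, which encodes a growth factor of granulocytes and macrophages, was at 0.56, or 0.32 (-0.20 to 0.84) without the top cells, and from -0.10 to 0.85 on leaving out single tables. Il5, Il2 and Foxp3 share sequence with other genes and are uncertain.

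**Figure D2:**
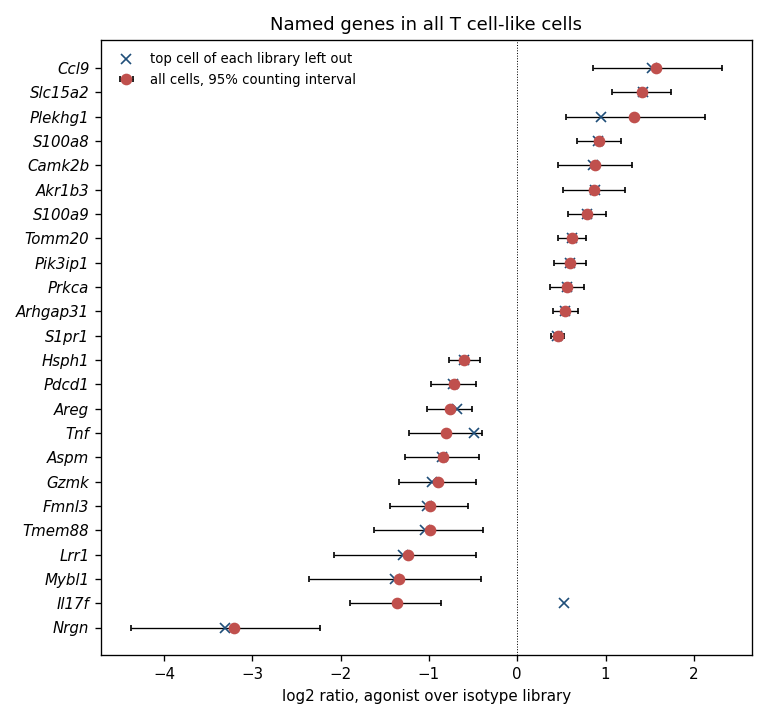
Log2 ratio of agonist over isotype counts in all T cell-like cells for the 12 named genes in each direction; circles use all cells with exact 95% counting intervals, and crosses leave out the cell with most counts of the gene in each library. S1pr1 sits at 0.46 with a narrow interval, and Il17f moves from -1.36 to 0.53 without its top cells.

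Of the metabolic and growth lists, those of mTORC1 and Myc targets and of oxidative phosphorylation were lower in T cells of the agonist library, while glycolysis (median 0.02), fatty acid oxidation (0.01), amino acid metabolism (0.03) and cholesterol and fatty acid synthesis (-0.0046) were near 0. Targets of mTORC1 and Myc, which drive cell growth, were lower in 16 of 20 members (median -0.19, percentile 0.01), with Hspe1 at -0.34 and Ran at -0.64 but Odc1 at 0.55. Genes of oxidative phosphorylation were lower in 43 of 55 members (median -0.11, below all 10000 random lists, or -0.06 with the Cd3e flag), with Atp5h at -0.42 but Cox7c at 1.38. These examples share sequence with other genes or pseudogenes and are uncertain. Type II interferon response genes were lower in 15 of 22 members (median -0.10, -0.14 to -0.05, percentile 0.65, or -0.17 over genes without shared sequence). The other lists lay between percentiles 1 and 99 in all T cells, among them those of type 2 helper cells (median -0.03), type 17 helper cells (-0.10), regulatory T cells (-0.07), inhibitory receptors (-0.08), T cell receptor signalling (-0.03) and T cell activation (0.02).

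Within CD4 T cell-like cells, the helper lineage, genes of activation were lower in 14 of 16 members in the agonist library (median -0.29, -0.42 to -0.16, below all 10000 random lists, or -0.19 at the finer resolution), with Egr1, an immediate early transcription factor, at -0.63. The type 1 helper program was lower in 8 of 9 members (median -0.33, percentile 0.10), including Il18rap, a chain of the interleukin 18 receptor (-0.55). The type 17 program was lower in 8 of 9 (median -0.28, percentile 0.56, or -0.17 at the finer resolution). Only 1 of the 9 intervals lay below 0, that of Il17f. Rora was at -0.12 (-0.29 to 0.04, or -0.05 without the isotype mouse 1 table), and Il17a at 0.30, or -0.34 without the agonist mouse 3 table. Tissue residency genes were lower in 7 of 9 (median -0.20, percentile 0.46, or -0.34 without a filter on low counts and -0.09 with doublets kept), with the transcription factor Bhlhe40 at -0.52 and the chemokine receptor Cxcr6 at -0.41. Cytotoxic genes were lower in 7 of 9 (median -0.26, percentile 0.78, or -0.55 with doublets kept), with Nkg7 at -0.74. Naive and memory genes were higher in 11 of 12 (median 0.19, percentile 99.2, or 0.37 with doublets kept), with Dapl1 at 0.54 and S1pr1 at 0.32 (0.49 with doublets kept). Type II interferon response genes were lower in 13 of 21 (median -0.13, percentile 0.84, or -0.06 under the first naming rule), with Cxcl10 at 0.98 but -0.62 with doublets kept. Intervals lay below 0 for 6 of the 16 activation, 3 of the 9 cytotoxic and 4 of the 21 interferon genes. On leaving out single tables, the CD4 medians ran from -0.52 to -0.19 for type 1, -0.44 to -0.20 for type 17, -0.27 to -0.06 for tissue residency, -0.52 to -0.11 for cytotoxic and -0.14 to -0.06 for type II interferon genes. Higher named genes were Slc15a2 (29 and 82 counts, 1.48), the splicing kinase gene Clk2 (1.497, or 0.82 without the isotype mouse 2 table), the ribosome assembly gene Utp20 (1.31), the DNA repair gene Dclre1c (1.38) and the mitochondrial carrier gene Slc25a40 (0.84). The 5 lower ones all rested in part on single isotype cells. Penk, the enkephalin precursor, had 73 counts of which 95.9% came from 1 cell, and Il17f went from -2.12 to 1.15 without its top cells and to 1.75 at the finer resolution. Areg, Tnf and the decoy receptor gene Il1r2 kept their sign without the top cells, at -1.58, -1.09 and -0.97 in place of -1.90, -1.64 and -1.30.

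The CD8 T cell-like class, the cytotoxic lineage, leaves out the cluster of dividing T cells (138 and 97 cells), which lay nearest to CD8 cells but stayed unnamed, so its values on cell division are those of the remaining cells. Its 947 and 879 cells came from a cluster led by Ccr9, Dapl1 and Ccr7 (436 and 519 cells), one led by Cd8a and Cd8b1 (336 and 253) and one led by Gzmk and interferon genes (175 and 107). In these cells, proliferation genes were lower in the agonist library in 18 of 19 members (median -0.91, -0.98 to -0.61, below all 10000 random lists). Top2a was at 76.6 CPM in the isotype library (67.5 to 86.5) and 36.6 in the agonist library (29.6 to 44.9), and the replication genes Pclaf and Lig1 were at -1.09 and -1.06. These values include the cluster led by Pdcd1 and Gzmk, most of whose cells left the CD8 class when doublets were kept, and the list's median was then -0.56. It came to -0.38 under a stricter filter on cells, -0.59 at the finer resolution and -0.04 under the first rule used to name clusters, where Top2a was at -0.16 and Lig1 at -0.33. The type 1 program was lower in 8 of 10 members (median -0.38, percentile 0.02), a value that came to -0.10 at the finer resolution, -0.14 with doublets kept and -0.22 under the first naming rule, with Cxcr3 at -1.10 and Il12rb1, a receptor chain for interleukin 12, at -0.94 (-0.64 and -0.54 at the finer resolution). Cytotoxic genes were lower in 9 of 12 (median -0.24, percentile 0.71), including the granzyme gene Gzmb (-0.66, or -0.01 under the first naming rule) and Nkg7 (-0.39, or -0.19 at the finer resolution), but their median was 0.06 under that rule, -0.0041 at the finer resolution and -0.095 with doublets kept. Oxidative phosphorylation genes were lower in 43 of 53 (median -0.21, below all 10000 random lists), or -0.08 under the first naming rule and -0.13 at the finer resolution.

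Higher in the CD8 cells of the agonist library were naive and memory genes (11 of 12, median 0.29, percentile 99.8, or 0.15 with doublets kept and 0.19 under the first naming rule), with S1pr1 at 0.55 (0.35 at the finer resolution) and Ccr7 at 0.49 (0.33 under that rule). So were genes that respond to glucocorticoids or cyclic AMP (10 of 12, median 0.23, percentile 99.7), with Tsc22d3, a glucocorticoid-induced regulator, at 0.36 (0.22 under that rule) and Dusp1 at -0.26 (-0.16). Neutrophil granule genes were higher in 3 of 6 members (median 0.37, percentile 99.1), with S100a8 at 1.02 and S100a9 at 0.80, although this median was -0.03 at the finer resolution, 0.19 without the isotype mouse 2 table and 0.80 over genes without shared sequence. Type II interferon response genes were lower in 14 of 21 members (median -0.03, percentile 23.03, and 0.04 at the finer resolution). Named higher genes besides S100a8 were Slc15a2 (1.31, 0.80 to 1.84), the endosomal adaptor gene Appl2 (1.41), the fatty acid elongase gene Elovl6 (0.89) and Cyth3 (0.91), and named lower genes besides Top2a, Pclaf and Lig1 were Raph1 (-1.62), an actin regulator, and Glrx, a glutaredoxin (-1.26, -1.82 to -0.72). Under the first naming rule, Appl2 was at 0.78, Elovl6 at 0.33, Cyth3 at 0.38, Raph1 at -0.10 and Glrx at -0.22. Ccr7 leads the cluster that held 436 of 947 CD8 cells in the isotype library and 519 of 879 in the agonist library.

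Regulatory T cell-like cells were few, at 150 and 108. Genes of cytotoxic effectors were higher in 6 of 6 members in the agonist library (median 0.82, 0.48 to 1.12, percentile 99.97, or 0.45 at the finer resolution and 0.48 without a filter on low counts), including Klrg1, a receptor of differentiated cells (63 and 102 counts, 1.11, or 0.73 without the agonist mouse 1 table), and Serpinb6b (1.19). Gzma had 8 and 93 counts (3.95, or 3.22 without the top cells, as 1 agonist cell held 47.3% of them, and 2.04 at the finer resolution). Tissue residency genes were lower in 4 of 6 members (median -0.30, percentile 0.90, or -0.19 with doublets kept), with Rgs2 at -0.49 and the early activation marker Cd69 at 0.42. Without the agonist mouse 1 table Rgs2 was at -0.29, and without the agonist mouse 2 table Cd69 was at 0.22. Type II interferon response genes were lower in 15 of 20 (2 intervals below 0, median -0.11, percentile 14.1, and -0.21 without the agonist mouse 2 table). Neutrophil S100a8 stood beside these values at 1.93, of which 55.0% of the agonist counts came from 1 cell.

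In gamma-delta T cell-like cells, proliferation genes were higher in 18 of 22 members in the agonist library (median 0.26, 0.18 to 0.45, percentile 99.95, or 0.15 with doublets kept and 0.41 without the agonist mouse 2 table), with the helicase gene Mcm3 at 0.56 and Top2a at 0.51 (0.28 without the agonist mouse 1 table). The dividing T cell cluster is outside this class too, and no difference between classes was tested. The class pools a cluster of 200 and 144 cells, with 3 gamma-delta markers detected, and one of 117 and 105 cells, with 9. Its values were not split between them. Gzmb was at 196 CPM in the isotype library (172 to 221) and 415 in the agonist library (376 to 457), from 84 and 86 cells. Immediate early genes, which tissue dissociation can induce, were higher in 16 of 19 members (median 0.16, percentile 99.1, or 0.10 with doublets kept), with Klf4 at 0.92. Intervals lay above 0 for 8 of the 22 proliferation and 6 of the 19 immediate early genes. Type II interferon response genes were lower in 12 of 21 (median -0.07, percentile 8.96, or -0.16 under the first naming rule). On leaving out single tables this median ran from -0.14 to -0.0003. Other higher genes were Slc15a2 (1.68), the nuclear lamina gene Lmna (1.02, 0.65 to 1.40), the kinase gene Mink1 (1.34) and Plekhg1 (1.48, or 1.11 without the top cells). Lower genes were Smad5, a mediator of bone morphogenetic protein signals (-1.76, -2.92 to -0.75), the endocytosis gene Ehd3 (-1.04), the RNA-binding gene Msi2 (-0.76), the anti-proliferative gene Tob1 (-0.91) and Ncln (-1.18).

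The third comparison asked how neutrophils and other leukocytes differed. In neutrophil-like cells, all 22 measured type II interferon response genes were lower in the agonist library (median -0.58, -0.64 to -0.52, below all 10000 random lists). Gbp2, a GTPase induced by interferon gamma, was at 1346 CPM in the isotype library (1308 to 1385) and 741 in the agonist library (713 to 770), and Irgm1, an immunity-related GTPase, was at 619 (593 to 646) and 370 (350 to 390). Type I interferon response genes were lower in 22 of 24 members (median -0.40, below all 10000 random lists), with Ifi47 at -0.79 and the viral RNA sensor Ifih1 at -0.77. The intervals of 2 members lay above 0, among them Oas1a, another sensor of viral RNA (21 and 74 counts, 1.77, uncertain for its shared sequence). Genes of class I antigen presentation were lower in 14 of 15 (median -0.33, below all 10000 random lists), with the immunoproteasome genes Psmb9 at -0.59 and Psmb8 at -0.58.

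Activation genes of neutrophils were lower in 15 of 18 members (median -0.21, percentile 0.01, or -0.12 over genes without shared sequence), including Cd274, which encodes the PD-1 ligand PD-L1 (2240 and 1549 counts, -0.57, uncertain for its shared sequence), and the chemokine genes Ccl3 (-0.50) and Ccl4 (-0.43). The neutrophil cluster led by Il1a, Csf1 and Cxcl3 held 656 of 1763 isotype and 543 of 2164 agonist neutrophils. Genes of NF-kB and TNF signalling were lower in 21 of 25 (median -0.11, percentile 0.19, or -0.19 with doublets kept and -0.07 without the isotype mouse 1 table), with Tnf at -0.48, and neutrophil chemoattractant genes in 5 of 8 (median -0.20, percentile 0.62, or -0.12 without a filter on low counts). Immediate early genes were lower in 18 of 22 (median -0.13, percentile 0.24, or -0.20 under plain totals), with Atf3 at -0.55 but Fosl2 at 0.29. Lists of growth and housekeeping were lower too, with 10 of 10 mTORC1 and Myc targets (median -0.42, percentile 0.27, or -0.25 with doublets kept), 7 of 9 heat shock genes (median -0.27, percentile 0.67) and 31 of 51 cytosolic ribosomal protein genes (median -0.24, below all 10000 random lists). Many members of these 3 lists share sequence with pseudogenes and are uncertain. Cytotoxic genes, which belong to NK and T cells, were lower in 6 of 7 members in neutrophil droplets (median -1.29, below all 10000 random lists), with Nkg7 at -1.44 and Ccl5, another transcript of those cells, at -1.15 (1 agonist cell held 32.3% of its counts). Ccl5 was at -0.30 with doublets kept and -1.74 without the agonist mouse 3 table.

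Granule and maturation genes were higher in 14 of 17 members (median 0.29) and neutrophil free RNA markers in 10 of 10 (median 0.42), both above all 10000 random lists. The granule list also holds Cxcr4, the receptor that retains neutrophils in bone marrow, at -0.54. Without the agonist mouse 2 table the medians were 0.18 and 0.25. The lists share genes, and without the free RNA genes the granule median was 0.086. Their members Retnlg and S100a8 also lead a neutrophil cluster of 1047 and 1564 cells, and Camp one of 60 and 57 cells. Rdh12, a retinol dehydrogenase (852 and 1671 counts, 0.93), leads the first of these as well. Other higher genes were Zfp523 (1.75), the actin nucleation gene Jmy (1.27), the microtubule gene Clasp1 (1.16) and Lin54 (1.20), and other lower genes were Prf1 (-1.60, or -0.23 with doublets kept, with 31.6% of its agonist counts in 1 cell), Aif1 (-1.58) and Pml, an interferon-induced nuclear body gene (-1.69, -2.64 to -0.83). The neutrophil genes fixed in advance differed little. Il1b was at 11498 and 11783 CPM (0.04, turning to -0.04 under plain totals), Cxcl2 at -0.12 (-0.20 under plain totals), Cxcr2, the receptor for neutrophil-attracting chemokines, at 0.12 (0.05), Csf3r at 0.19 and Cxcl1 at 0.16 (-0.14 to 0.47). Cxcr2 and Csf3r share sequence with other genes and are uncertain.

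The lower type II interferon response extended over other myeloid cells of the agonist library. It was lower in 22 of 23 members in classical monocyte-like cells (median -0.59, -0.76 to -0.45), in 23 of 23 in nonclassical monocyte-like cells (-0.58, or -0.37 over genes without shared sequence), in 23 of 23 in interstitial macrophage-like cells (-0.38) and in 21 of 21 in conventional dendritic cell type 2-like cells (-0.29), each below all 10000 random lists. Cxcl10, a chemokine that attracts Cxcr3-bearing cells, was at 575 CPM in the isotype monocytes (544 to 608) and 228 in the agonist monocytes (208 to 250). Neutrophil free RNA markers had medians of -0.57 in classical and -0.25 in nonclassical monocyte-like cells (-0.44 to -0.21, 6 of 7 members lower). Type 2 innate lymphoid-like cells were at -0.48 (14 of 17, 6 intervals below 0), migratory dendritic-like cells at -0.27 (14 of 17, percentile 0.42) and B cell-like cells at -0.21 (15 of 19, 5 intervals below 0, percentile 0.03). In NK cell-like cells the interval of the median included 0 (-0.12, -0.18 to 0.01, percentile 0.82, or -0.05 without the agonist mouse 1 table). There 1 interval lay below 0 and 2 above, those of Cxcl10 (0.78) and Tgtp1 (1.03, or 0.64 with doublets kept, uncertain for its shared sequence). Over genes without shared sequence the median in NK cell-like cells was -0.18 (-0.23 to -0.04, percentile 0.08). Plasmacytoid dendritic-like cells were at -0.08 (-0.26 to 0.08, percentile 23.8), or -0.18 to 0.03 on leaving out single tables, and basophil or mast cell-like cells at 0.15 (-0.09 to 0.42, percentile 88.7, or -0.09 without the isotype mouse 1 table). Alveolar macrophage-like cells went the other way, with 9 of 10 members higher (2 intervals above 0, median 0.36, 0.12 to 0.66, percentile 99.6), from 37 and 29 cells. Leaving out single tables gave 0.18 to 0.69 there. Over all CD45+ cells the median was -0.27 (-0.30 to -0.26) with 23 of 23 members lower.

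**Figure D3:**
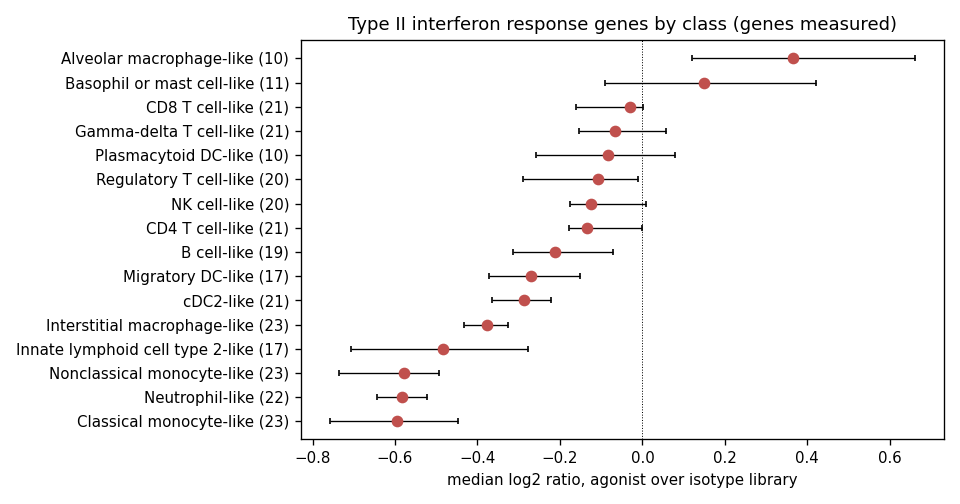
Median log2 ratio of agonist over isotype for type II interferon response genes in each cell class, with the number of genes measured in parentheses. Bars are 95% intervals from redrawing the counts of these genes with Poisson error, and cover counting error only. Neutrophil-like cells and both monocyte classes lie at -0.59 to -0.58, and alveolar macrophage-like cells at 0.36.

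Interstitial macrophage-like cells of the agonist library had more Id3, a transcriptional regulator (14.3 CPM, 11.4 to 17.7, against 40.6, 35.4 to 46.4), more Ccl8, a chemokine (1.69, or 1.49 without the top cells), and more Rnase2a (1.36), Akr1b3 (1.55) and Ccr7 (1.19, or 0.63 with doublets kept). Neutrophil free RNA markers were higher in these macrophages in 6 of 7 members (median 0.44, 0.13 to 0.55, percentile 99.89). The cells had less Edn1, the endothelin precursor (-1.33, -1.76 to -0.91), Tlr12 (-1.49), the collagenase gene Mmp13 (-1.64, or -0.84 with doublets kept), Zfp637 (-1.54) and Cxcl10 (-0.73). Classical monocyte-like cells had less Acod1, the enzyme that makes itaconate, at 88.6 CPM (76.6 to 102) against 18.9 (13.4 to 26.0), and less Mmp9 (-2.94), AA467197 (-1.93), Csf1 (-2.30) and Upp1 (-1.98), and more Slc15a2 (1.32, or 0.83 without the isotype mouse 2 table), Ifi214 (1.14), Nkg7 (1.29, or 0.75 with doublets kept), Dab2 (1.29, or 0.76 at the finer resolution) and Id3 (0.87). Neutrophil free RNA markers were lower in these monocytes in 6 of 7 members (median -0.57), and Mmp9, Csf1 and Upp1 are also transcripts of neutrophils. Acod1 is among the leading genes of an unnamed cluster of 14 and 21 cells led by S100a8 and S100a9. Single cells held 35.4% of the agonist counts of AA467197, 6 of the 20 isotype counts of Nkg7 in monocytes and 30.8% of the agonist counts of Mmp13 in macrophages. Over all CD45+ cells, Adamts13, which cleaves von Willebrand factor, had 79 counts from 66 isotype cells and 13 counts from 13 agonist cells (-2.54, -3.51 to -1.68). Most other genes named for all cells rested on single cells, such as the mast cell protease gene Mcpt1, whose 68 agonist counts came from 1 cell, Ccl20, with 54 isotype counts of which 77.8% came from 1 cell, and Jchain, the joining chain of secreted antibodies (23 and 359 counts, 46.2% in 1 cell, with a log2 ratio of -0.54 once doublets were kept). The remaining ones were Il12b (1.98), Prss34 (1.499), which also leads the basophil or mast cell-like cluster, Akr1c18 (1.73, or 1.08 without the agonist mouse 1 table), Fabp1 (-1.96), Mmp13 (-1.56, or -1.01 without the agonist mouse 1 table) and Nbea (-1.39).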

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

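Of the tests in this part, the one of whether the treatment acts on ribosomal protein genes in some cell types was chosen only after its result was seen, and the patterns were found in the same data.

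Cell records that the authors' filter left out, 1342 of the isotype library (10.8%) and 1512 of the agonist library (11.01%), carried a signal that the comparisons do not use. Marker genes of proliferating cells reached 2106.6 CPM in the isotype records and 1756.0 CPM in the agonist records, against 646 and 530 in the kept cells. The left-out records of the libraries were unlike each other, with a median of 12256.5 counts and 3779.5 genes in isotype and 746.5 counts and 446.0 genes in the agonist library. The cause was not tested, and the proliferation values of the T cell classes cover kept cells only.

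The first pattern concerns ribosomal protein genes and their pseudogenes, which filled most places in the ranking of genes before those with shared sequence were left out. Summed over a gene and its named pseudogenes in 49 families, the median absolute log2 ratio was 0.0866. It was 0.626 for single pseudogenes and 0.268 for the parent genes alone. Reads divided differently between near-identical copies may therefore account for much of the pattern. All 442 such genes kept their sign in each of the 3 table pairs (100%), but this decides nothing about a difference between tables, as these are overlapping parts of 1 pool and the genes were picked from the pooled counts. In other coding genes of B cells, those with shared sequence had absolute ratios 1.0312 times those of matched genes (0.957 to 1.13). The bound set in advance for excluding shared sequence lies above this ratio but within its interval, so the question is left open. The pattern's genes had a median spread over 10 classes of 0.1394 against 0.239 for interferon genes, a gap with an upper bound of -0.0239. Beyond counting error the spread was 0.070 against 0.18. Of 161 genes with an absolute mean over 0.5, 160 had the same sign in all classes. As these genes were picked by their mean over the same classes, a shared sign was likely in advance and is no separate evidence. An action of the treatment on some cell types stays open, as the median absolute mean of 0.46 fell short of the 0.5 asked by the rule. A difference between the preparation of the libraries was not tested.

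The second pattern is the lower type II interferon response in the agonist library. Without the genes named Gbp, Irgm or Tgtp the median over all CD45+ cells was -0.2496 (-0.274 to -0.231, 13 of 13 members lower). The GTPase genes Igtp and Iigp1 stayed in this set. Without them and without members with shared sequence it was -0.233 (-0.260 to -0.211, 10 members). Both values argue against reads shared between paralogs as the whole cause. Within neutrophil cluster 1 the median was -0.70 and within cluster 5 it was -0.1391 (-0.215 to -0.079), which leaves open how much a different mix of clusters contributes. Less interferon gamma transcript cannot be told apart from other causes, since Ifng was at -1.11 in T cells, in part from 1 cell and with shared sequence, but at -0.1155 (-0.270 to 0.039) in NK cells. An effect of the treatment stays possible as a hypothesis, and with 1 library per treatment it cannot be told apart from a difference between libraries.

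The third pattern is the higher expression of naive and memory genes in T cells of the agonist library. With 11 T cell clusters weighted equally in both libraries the median was 0.0934, against 0.268 for the pooled cells. A different mix of clusters could account for most of the pattern, but the value lies above the bound set in advance (0.0894), which keeps this open. The clusters were drawn from the same cells, and Ccr7, Dapl1 and Igfbp4 of this list lead some of them. Weighting the clusters can therefore shrink the ratio whatever the cause. Within single clusters the median ran from -0.16 to 0.68, and only the lowest lay below 0. RNA from other cells is not weighed here. Whether the treatment changed the mix of clusters was not testable with 1 library per treatment.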

How the results depend on the processing

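Several alternatives here were chosen only after the data had been seen, namely plain totals, TMM or lists over genes without shared sequence, the first naming rule, the authors' Cd3e flag and the top cells left out, as were some uses of the others.

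No paired analysis was possible because the numbered tables of a treatment hold the same pooled cells and no value came from a test. For the same reason DESeq2, the replicate block, the exact permutation test, fry, camera and an estimated correlation gave no value. Leaving out a table removes part of the cells of a pool, not a mouse. Of 243 recomputed shares 238 stayed within their interval, as did 4312 of 4545 gene ratios, 775 of 860 list medians and 56 of 61 ratios of Pdcd1, while 5, 215, 82 and 4 moved beyond it and 0, 18, 3 and 1 changed sign from a called value. RLE factors moved 1 gene and no list. The alternative without a filter on low counts was computed for lists only. Depth limits what the smallest classes can show, with 37 and 29 alveolar macrophage-like cells. The cause of the shifts below was not tested, except that leaving out the top cell shows where single cells carried a value.

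With doublets kept, Pdcd1 in CD8 cells was 0.52, Ifng 0.26 and Gzma 0.11 there, Gzma in neutrophils 0.37, Cxcl10 in CD4 cells -0.62, Jchain over all cells -0.54 and Il1b in neutrophils -0.031. List medians in neutrophils were then -0.19 (NF-kB), -0.51 (type I interferon), -0.71 (type II), -0.27 (chemoattractants), -0.16 (immediate early genes) and 0.35 (free RNA). The type II median was -0.49 in nonclassical monocytes and 0.011 in CD8 cells. In CD4 cells naive genes were at 0.37 and cytotoxic genes at -0.55. In CD8 cells the type 1 program was at -0.14, naive genes at 0.15, cytotoxic genes at -0.095 and proliferation at -0.56, and gamma-delta proliferation was at 0.15.

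At Leiden resolution 2, CD8 cells had log2 ratios of -0.69 of kept cells and -0.49 of T cells, Pdcd1 was -1.47 in CD4 and -0.52 in CD8 cells, Il17f in CD4 cells 1.75, and the type II median in neutrophils -0.70. The CD8 medians were -0.10 (type 1), 0.22 (naive), -0.0041 (cytotoxic), 0.044 (type II), -0.13 (oxidative phosphorylation), -0.59 (proliferation) and -0.026 (granules), and the cytotoxic median of regulatory T cells was 0.45. Under the first naming rule, CD8 cells were at -0.62 of kept cells and -0.36 of T cells, gamma-delta cells at -0.0087 of T cells, Pdcd1 in gamma-delta cells at 0.18 and Gzma in CD8 cells at 0.21. The CD8 medians were -0.22 (type 1), 0.19 (naive), 0.062 (cytotoxic), 0.013 (type II), -0.081 (oxidative phosphorylation) and -0.040 (proliferation), the gamma-delta type II median was -0.16 and the naive median of all T cells 0.31.

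The authors' Cd3e flag, taken in place of the T cell class, covers kept cells of any class. With it, values were -1.16 for Pdcd1, -1.29 for S100a8, -1.20 for S100a9, -2.05 for Retnlg, -0.36 for Il17a and 0.19 for Il4. The medians were 0.18 (naive), -0.063 (oxidative phosphorylation), -1.02 (granules) and -1.51 (neutrophil free RNA). Without the top cells, Il17f was 1.15 in CD4 cells and 0.53 in all T cells.

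Under plain totals, Il1b in neutrophils was -0.035, and the neutrophil medians were -0.18 (NF-kB), -0.48 (type I), -0.65 (type II), -0.27 (chemoattractants), -0.40 (class I), -0.20 (immediate early), -0.31 (ribosomal) and 0.35 (free RNA). Oxidative phosphorylation was -0.24 in CD8 and -0.15 in all T cells, where naive genes were 0.23. With unshared genes only, neutrophil medians were -0.52 (type I) and -0.12 for chemoattractants and activation alike. The type II medians were -0.30 in interstitial macrophages, -0.37 in nonclassical monocytes, -0.18 in NK cells and -0.17 in all T cells, and granule genes were 0.80 in CD8 and 0.65 in all T cells. Without a filter on low counts, type I genes in neutrophils were -0.46, chemoattractants -0.12, residency in CD4 cells -0.34 and cytotoxic genes in regulatory T cells 0.48. Without free RNA genes, granule genes were 0.086 in neutrophils and -0.18 in all T cells. Under the stricter filter, proliferation in CD8 cells was -0.38 and neutrophil free RNA 0.38 in neutrophils.

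Leaving out each table in turn gave -0.10 to 0.85 for Csf2 in all T cells and -0.39 to 1.41 for Ube2c in gamma-delta cells. List medians ranged in neutrophils from -1.61 to -0.93 (cytotoxic), 0.25 to 0.48 (free RNA), -0.14 to -0.073 (NF-kB), -0.23 to -0.145 (chemoattractants) and 0.18 to 0.34 (granules). They ranged in all T cells from -0.13 to -0.089 (oxidative phosphorylation), -0.29 to -0.145 (proliferation) and -0.14 to -0.071 (type II). The ranges were -0.52 to -0.11 (cytotoxic) and -0.44 to -0.20 (type 17) in CD4 cells, and -1.02 to -0.67 (proliferation) and -0.17 to -0.029 (type II) in CD8 cells. Type II medians ranged from -0.30 to -0.27 over all CD45+ cells, 0.18 to 0.69 in alveolar macrophages and -0.094 to 0.53 in basophils or mast cells.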

Other observations

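None of the values in this part comes from a test. Which of the genes named by the ranking rule to give here was chosen after the values were seen. So were the list of plasma cell free RNA and Igha. Of the genes given for B, NK, nonclassical monocyte, dendritic and basophil or mast cell-like cells, Cxcl9 alone was recomputed under the other filters and clusterings and on leaving out tables.

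Slc15a2, the peptide transporter gene, was named by the ranking rule as higher in the agonist library in 6 comparisons, namely all T cells, CD4, CD8 and gamma-delta T cell-like cells, B cell-like cells (117 and 239 counts, 0.92) and classical monocyte-like cells. Free RNA markers of plasma cells, the antibody-secreting end stage of B cells, were higher over all CD45+ cells in 8 of 9 members (median 0.23, percentile 99.04). Most are immunoglobulin genes, and no cluster was named as plasma cells. The list was picked here from the 16 of 37 lists beyond the percentiles in that comparison. In B cell-like cells it had 3 members higher and 4 lower (median -0.04, percentile 39.96). Single cells weigh on the list over all cells, since 1 agonist cell held 88.1% of the 749 counts of Igha, the constant region of immunoglobulin A. The log2 ratio of Igha was 0.59 without the top cells, and that of Jchain, another member, was -0.54 with doublets kept. In NK cell-like cells, the integrin gene Itgb3 (69 and 136 counts, 1.01) and Tmem176b (1.35) were higher, and Nbea (-1.39) lower, in the agonist library. Tmem176b also leads a gamma-delta T cell cluster.

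Nonclassical monocyte-like cells, which patrol the vessel wall, had less Ccl2, a monocyte-attracting chemokine (296 and 87 counts, -1.80, -2.16 to -1.45), Cxcl9 (412 and 179 counts, -1.24, or -0.75 without the isotype mouse 2 table, with 45.3% of the agonist counts in 1 cell) and Clec5a (-1.28) in the agonist library. Neutrophil free RNA markers were lower in this class as well, in 6 of 7 members (median -0.25, -0.44 to -0.21). Clec5a and Cxcl3 also lead a neutrophil cluster, Ccl22 the migratory dendritic cell cluster and Ccl2 an unnamed one. In conventional dendritic cell type 2-like cells Ccl2 was lower as well (81 and 31 counts, -1.58), with Cxcl3 at -2.62 (1 isotype cell held 69.9% of its counts, and the ratio was -1.96 without the top cells) and Ccl22, which attracts Ccr4-bearing T cells, at -0.89 (-1.08 to -0.70, or -0.75 without the top cells). Basophil or mast cell-like cells had less of the immediate early genes Fosb (1731 and 1380 counts, -0.62) and Egr2 (-1.10). B cell-like cells had less Lta, which encodes lymphotoxin alpha (36 and 14 counts, -1.48), and more Dclre1c (0.88), which was also higher in CD4 T cell-like cells.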
